A study of Mus musculus with 4 samples.

How the data were processed

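Ribosome footprints were sequenced from the mouse embryonic stem cell line E14, grown with serum and leukemia inhibitory factor on gelatin, per the labels' protocols. Ribosome profiling digests a cell lysate with a nuclease and sequences the short RNA pieces that ribosomes shield, so that the reads of a gene follow both the amount of its mRNA and how densely ribosomes sit on it. Lysates were digested with RNase I, footprints were purified on size-exclusion columns, ribosomal RNA was depleted, and libraries were made with a small RNA kit, per the labels' protocols. 4 libraries were used here: 2 from cells kept in DMSO, the solvent control, and 2 from cells kept in 1 µM PD, both for 3 passages. The labels give the compound only as PD, and they do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

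The deposited values are FPKM, fragments scaled by transcript length and by the mapped fragments of the library, in 1 table of 25170 genes for the 4 libraries, with a lower and an upper confidence bound and a status per value, laid out as Cufflinks writes them, per the file headers. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, STAR and Cufflinks and the mouse build mm10, with versions not given in the sources used here. How reads that match several places were shared between genes, and whether footprints were restricted to coding sequence, is not given in the sources used here. 1 gene, Rmrp, carried a failed status and was left out. Gene types and symbols were looked up in a RefSeq table of GRCm38.p6, the assembly that mm10 shows, where 24976 of the 25170 symbols were found. Loci are those of the deposited table, and because its starts equal the RefSeq starts minus 1 for 14625 genes, 1 was added to each start. A locus there can span neighbouring genes that Cufflinks joined.

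Depth is not stated in the table, so it was read from the values. For a gene counted in whole reads, its FPKM values are whole multiples of what 1 read is worth in each library, and the libraries' steps give their relative depth. With a tolerance of 0.02 reads, whole reads were recovered for 70.9% of the 10161 genes above 0 in all 4 libraries, against 1.25% when wrong library steps were used. Recovery was less specific for the 1809 genes above 0 in 2 libraries, at 85.9% against 10.2% with wrong steps. The reads given are the smallest whole numbers that fit. On simulated data of 12000 genes, 98.9% had reads recovered, 91.8% of these equalled the true reads, and 1.97% of genes without a common step were given reads all the same. Relative to DMSO replicate 1, the depth was 1.42 for DMSO replicate 2, 0.464 for PD replicate 1 and 0.201 for PD replicate 2. Intervals and exact tests on reads cover counting error only, since no molecular identifiers are named and reads are then not independent molecules.

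Genes with a mean of at least 1 FPKM over the 4 libraries were tested, which kept 9741 genes, of which 8861 were protein-coding and 605 were miRNA or snoRNA genes. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with group as the only term and 2 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. No other normalization was applied. 25 gene lists were fixed before the data were examined, and the 23 lists with at least 2 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists by Benjamini-Hochberg. Camera with an estimated correlation and fry were run beside it. No 2-cell-like state gene and no mitochondrially encoded gene was tested.

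The genes named were set by a rule before the data were examined. Per direction, it takes the 12 largest differences among genes that pass, have both PD libraries on the same side of both DMSO libraries, have a mean of at least 5 FPKM and do not have the symbol of an unnamed model or small RNA. Small RNAs were recognized by symbols such as Mir, Snor and Scarna, so the noncoding RNAs Rnu11 and Terc were kept. Where fewer than 12 pass, the places are filled with genes of unadjusted p under 0.01 that meet the other criteria, and all 24 places were filled in this way. It also takes 16 genes of the pathway and of pluripotency, of which 1 is not reported here, and up to 4 members of each list with the largest differences.

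The fit was tested on simulated data with the means and spreads of the 9741 genes. Of 100 genes changed by 1 log2 unit and 100 changed by 2, 0% passed, while 3 unchanged genes did. Of 200 genes changed by 4, 84% passed, beside 18 unchanged genes. With the spread set to 0.1 log2 units, 100% of the genes changed by 1 and by 2 passed. A list shifted by 0.5, with noise drawn independently for each gene, reached a camera adjusted p of 7.42e-08. Lists of correlated genes were not simulated.

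The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5, median, quantile and trimmed-mean scaling, other variance settings, a table without small RNA, unnamed, mitochondrial and histone genes, the replicate number as a block, an adjusted p of 0.1, and each library left out in turn. 4 were chosen after the data were seen: protein-coding genes only, limma's voom on recovered reads for genes with at least 20 reads, and, for the naive pluripotency list, camera with an estimated correlation under 2 of the settings above. Exact binomial tests used SciPy 1.17.1. No RNA-seq libraries were analysed here, so translation per mRNA was not estimated.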

Results

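Ribosome-protected RNA was measured in E14 mouse embryonic stem cells, a line derived from the inner cell mass, after 3 passages in DMSO or in 1 µM PD. The comparison of the groups, with 2 libraries each, addresses the part that the kinase Mek plays in gene regulation after transcription, and the series is about Dcp1a, a cofactor of the enzyme that removes the mRNA cap. FPKM were above 0 for 13891 and 14764 genes in the DMSO libraries and for 12662 and 11522 genes in the PD libraries, noncoding genes included. The PD libraries were shallower: relative to DMSO replicate 1, depth was 1.42 in DMSO replicate 2, 0.464 in PD replicate 1 and 0.201 in PD replicate 2. Over 5796 protein-coding genes with recovered reads in every library, the median gene had 75 and 106.5 reads in the DMSO libraries and 36 and 15 in the PD libraries. Depth thus went with treatment in these libraries, and PD replicate 2 carries the largest counting error. miRNA genes, whose short models inflate the unit, took between 95.1% and 97.7% of the FPKM sum of each library. Reads on miRNA, snoRNA and other noncoding genes are not evidence of translation, and whether ribosomes shielded them was not tested. Across the 8861 protein-coding genes tested, log2(FPKM + 1) correlated at r = 0.949 between the DMSO libraries, at 0.907 between the PD libraries and at 0.895 to 0.938 between groups. These are correlations across genes, which are not independent replicates.

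**Figure D1:**
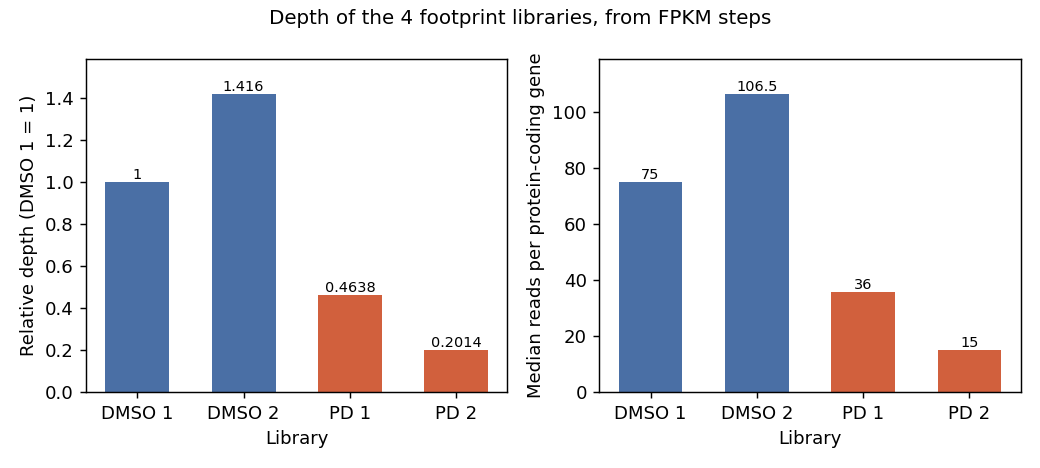
Depth of each footprint library, with relative depth (DMSO replicate 1 set to 1) on the left and the median recovered reads per protein-coding gene (5796 genes) on the right. DMSO libraries are blue and PD libraries are orange, and PD replicate 2 is the shallowest, at 0.201 and 15 reads.

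No protein-coding gene passed the test between PD and DMSO. The genes with the largest log2 differences among those that met the naming rule are therefore given as values. Footprints on Klhl13, an adaptor of a cullin ubiquitin ligase on the X chromosome (mm10, chromosome X, 23219271 to 23365082), had 251 ± 13.1 FPKM in DMSO and 69.4 ± 9.97 in PD (SD, n = 2), a log2 difference of -1.84 with an SE of 0.26 (limma adjusted p = 0.352). Mboat1, a membrane-bound acyltransferase (chromosome 13, 30136490 to 30246694), stood at 86.1 and 40.9 FPKM in the DMSO libraries and at 5.39 and 1.2 in the PD libraries. Epcam, an adhesion protein of epithelial and pluripotent cells (chromosome 17, 87635979 to 87651127), had 78.7 ± 14.5 FPKM in DMSO and 26.7 ± 1.34 in PD (SD, n = 2), with a limma adjusted p of 0.614. The tight junction protein Cldn6 had 38.3 ± 0.0653 and 11.9 ± 2.87 FPKM in DMSO and PD (SD, n = 2). Ap1m2, the epithelial subunit of a clathrin adaptor, had 16.6 FPKM in DMSO and 1.96 in PD, with the smallest adjusted p of any protein-coding gene (limma, 0.123). The other genes with the largest downward differences were Jade3, Lsr, Dcaf4, Magohb, Rhebl1, Bloc1s4 and the telomerase RNA Terc, with log2 differences from -1.81 for Terc to -1.47 for Bloc1s4. None of these 12 genes passed.

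In the other direction, Mrpl13, a protein of the mitochondrial ribosome, had 124 ± 19.5 FPKM in DMSO and 370 ± 111 in PD (SD, n = 2), with a log2 difference of 1.54 and an SE of 0.34 (limma adjusted p = 0.717). Slc25a20, the mitochondrial carnitine carrier, had 14.4 and 44.6 FPKM in DMSO and PD, and the cell-surface proteoglycan Gpc4 had 9.51 and 28.5. Rpl39l, a ribosomal protein gene with close copies that can share its reads, had 26.2 and 78.5 FPKM. Rnu11, a small nuclear RNA of the minor spliceosome, had 3187 and 18102 FPKM. Low-level genes made up most of the rest: Olfr1461, Catip, Arhgef17, Aard, Gprc5a, Cmtm7 and Ccl25 all had under 10 FPKM on average in DMSO. Catip rested on 5 and 6 recovered reads in the DMSO libraries and on 20 and 8 in the PD libraries. None of these 12 genes passed, and their adjusted p-values ran from 0.219 for Catip to 0.717 for Aard and Mrpl13 (limma).

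**Figure D2:**
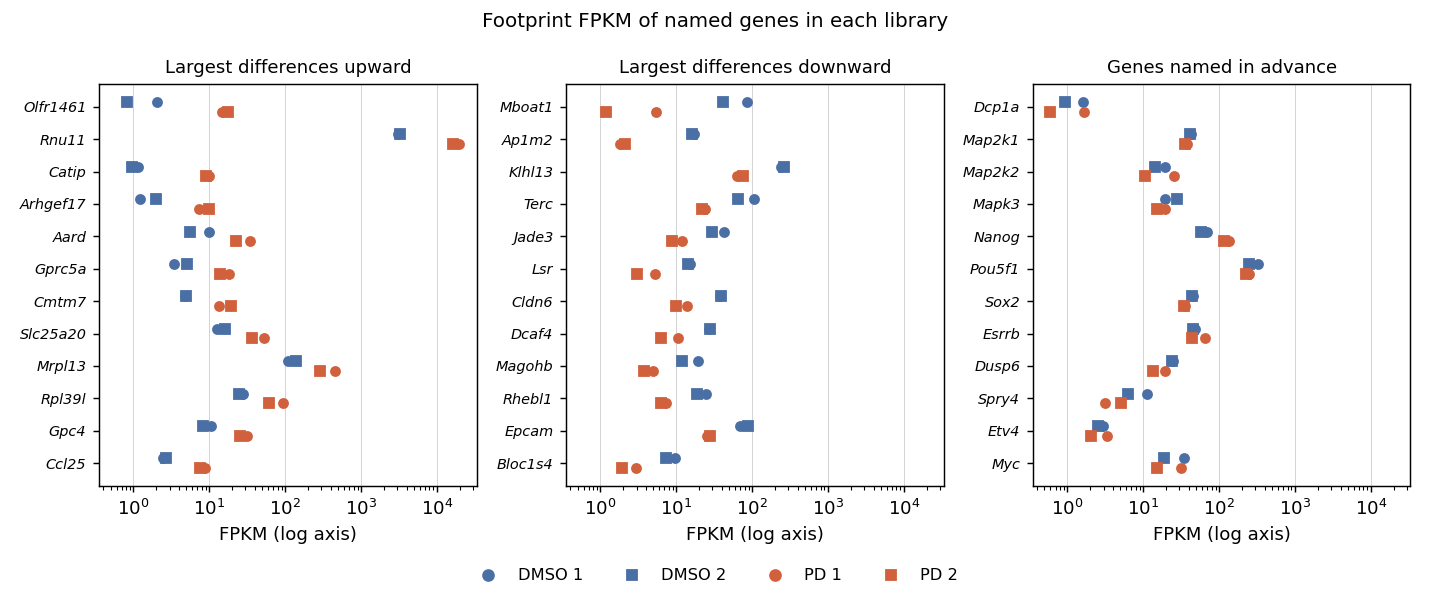
FPKM per library (log axis) for the 12 genes with the largest upward differences, the 12 with the largest downward differences and 12 genes named in advance. Rnu11 and Terc are noncoding RNAs. Circles are replicate 1 and squares replicate 2, DMSO in blue and PD in orange; Nanog lies at 70 and 57.1 FPKM in DMSO and at 136 and 116 in PD.

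The genes that did pass were all miRNA or snoRNA genes listed at 0 in both libraries of 1 group. limma gave 3 genes higher and 22 genes lower in PD among 9741 tested, with 561 genes at an unadjusted p under 0.05, where 487 would be expected by chance. Mir3064 (chromosome 11) was listed at 0 in both DMSO libraries and at 4379 and 7204 FPKM in the PD libraries, which corresponds to 7 and 5 recovered reads (limma adjusted p = 0.00315). Mir8109 and Mir378b were the other 2 genes higher in PD, with 6 and 1 and with 1 and 1 recovered reads. Snora21, lower in PD, had 389 and 366 FPKM in the DMSO libraries, with 3 and 4 recovered reads, and was listed at 0 in both PD libraries. Mir15a, a miRNA of the Mir15 and Mir16 cluster, had 1 recovered read in each DMSO library and was also listed at 0 in both PD libraries. Over the 17 lower genes with recovered reads, the total over all libraries ran from 2 to 8 recovered reads. Recovered reads are the smallest whole numbers that fit, so the true reads of a gene may be a multiple of them. The genes that passed were above 0 in 2 libraries, a class where wrong library steps also gave reads for 10.2% of genes. Without DMSO replicate 1, and without DMSO replicate 2, 0 genes passed in either direction, against 18 higher and 30 lower without PD replicate 1 and 27 higher and 26 lower without PD replicate 2. Among protein-coding genes alone, and with voom on recovered reads, neither of which keeps any of these 25 genes, 0 genes passed, with 606 and 438 genes at an unadjusted p under 0.05 (limma).

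ERK target and feedback genes, which are transcribed when the kinase below Mek is active, did not pass as a list. Of 22 tested members, 7 had both PD libraries below both DMSO libraries, 1 had both above, and 14 overlapped. Over all 9741 genes tested, 35.8% had no overlap in either direction, where 33.3% would be expected by chance. That share is the background for the same counts of every list below. The median log2 difference was -0.24 (camera adjusted p = 0.395). Ier3, an immediate early gene, had 12.9 FPKM in DMSO and 3.83 in PD. The feedback inhibitor Spry2 had 18.3 and 8.07 FPKM, and its relative Spry4 had 8.81 and 4.07. Dusp6, a phosphatase that acts on ERK, had 24.3 ± 0.41 FPKM in DMSO and 16.6 ± 4.19 in PD (SD, n = 2). Egr1 was at 2.18 and 1.65 FPKM in the DMSO libraries and at 1.14 and 0 in the PD libraries. Jun went the other way, at 0.349 FPKM in DMSO and 1.65 in PD. It had 1 and 2 recovered reads in the DMSO libraries and 3 and 1 in the PD libraries. These are the smallest whole numbers that fit, and its true reads may be a multiple of them. Etv4 and Myc differed by less than their replicates did. 0 members passed over all genes, and 0 when adjusted over the list alone.

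None of the kinases themselves and none of the decapping factors passed. Map2k1, which encodes Mek1, had 41.6 ± 0.993 FPKM in DMSO and 37.1 ± 1.73 in PD (SD, n = 2), and Map2k2 had 16.8 ± 3.29 and 18.1 ± 10.4. Mapk3, which encodes ERK1, had a log2 difference of -0.44 (limma adjusted p = 0.837). The MEK-ERK pathway components had a median of -0.04 over 22 tested members, with Grb2, Fgfr2 and Sos1 the lowest. Grb2 had 3.8 and 5.62 FPKM in the DMSO libraries, 3.59 in PD replicate 1 and 0 in PD replicate 2, the shallowest library. Dcp1a was covered thinly, at 1.6 and 0.93 FPKM in the DMSO libraries and 1.63 and 0.594 in the PD libraries, from 40, 33, 19 and 3 recovered reads. Its log2 difference was -0.13 with an SE of 0.45 (limma adjusted p = 0.97), so the difference was smaller than its SE. Its sign turned with quantile normalization (0.18) and in the table rescaled without small RNA genes (0.02). The 47 tested mRNA decapping and decay factors had a median of -0.05 (camera adjusted p = 0.999), with 8 members higher and 5 lower in both PD libraries. Ddx6, a helicase of decapping complexes, had 16.9 FPKM in DMSO and 30.6 in PD, and Cnot4, a ubiquitin ligase of the deadenylase complex, had 3.5 and 7.2. Lsm7 and Pan3 had log2 differences of -0.86 and -0.73, with libraries that overlapped between the groups. This list's median turned above 0 with quantile normalization (0.04) and in the rescaled table (0.25), and 0 members passed, over all genes or adjusted over the list alone.

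Naive pluripotency genes, which mark the ground state of embryonic stem cells, lay higher in PD as a list, with a median log2 difference of 0.30 over 26 tested members. The list did not pass over the 23 lists (camera p = 0.00736, adjusted p = 0.169), and with an estimated correlation the p was 0.191. 9 members had both PD libraries above both DMSO libraries and 1 had both below. Nanog, a core factor of the naive state (chromosome 6, 122707489 to 122714633), had 63.6 ± 9.09 FPKM in DMSO and 126 ± 13.7 in PD (SD, n = 2), a log2 difference of 0.98 with an SE of 0.26 (limma adjusted p = 0.803). Tbx3 had 4.84 and 12.8 FPKM, Mras 2.37 and 6.03 and Tet2, an enzyme that oxidizes methylated DNA, 3.2 and 6.7. Dppa3 was the exception, at 3.5 and 2.23 FPKM in the DMSO libraries and listed at 0 in both PD libraries. Klf4 and Esrrb overlapped between groups. 0 members passed, over all genes or adjusted over the list alone. Without DMSO replicate 1 the list passed (median 0.39, camera adjusted p = 0.00706), as it did without the filter on low genes (adjusted p = 0.0206). Both calls were lost with an estimated correlation (adjusted p = 0.919 and adjusted p = 0.984). The median of the naive pluripotency genes was 0.16 without DMSO replicate 2, 0.19 without PD replicate 1, 0.17 with voom and 0.65 in the rescaled table, and the list passed in none of these.

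Formative and primed pluripotency genes, which mark cells leaving the naive state, had a median of -0.43 over 16 tested members and did not pass (camera adjusted p = 0.395). 6 members were lower and 2 higher in both PD libraries. Sox4 had 14.5 and 3.5 FPKM in the DMSO libraries and 1.73 and 2.58 in the PD libraries. Pim2 and Tcf15 had log2 differences of -0.93 and -0.77, and the methyltransferase Dnmt3b had 29.9 FPKM in DMSO and 21.1 in PD. Ncam1, an adhesion molecule, went the other way, with 3.64 and 10.2 FPKM. Fgf5, the common marker of this state, was at 0.0938 FPKM in DMSO replicate 1, was listed at 0 in the other libraries and was not tested. Core pluripotency genes had a median of -0.25 over 15 members: Pou5f1 had 286 ± 57 FPKM in DMSO and 237 ± 13.1 in PD (SD, n = 2), Sox2 had 45.1 and 35.3, and L1td1 had 216 and 319. 0 members of either list passed, over all genes or adjusted over the list alone.

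**Figure D3:**
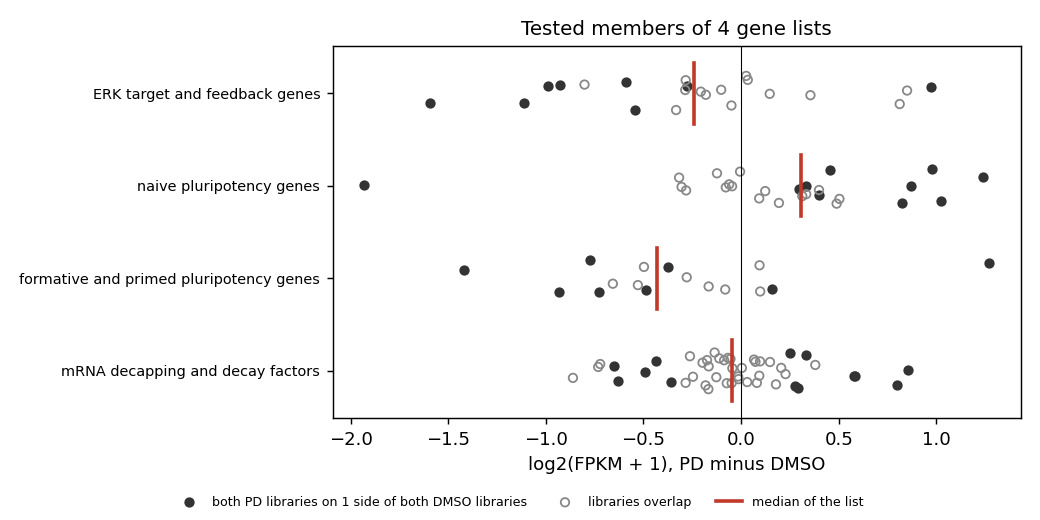
log2(FPKM + 1) differences, PD minus DMSO, of the tested members of 4 gene lists, with 1 point per gene and the list median as a red line. Filled points are genes whose PD libraries lie on 1 side of both DMSO libraries; the medians are -0.24, 0.30, -0.43 and -0.05 from top to bottom, and none of the lists passed.

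None of the other 19 tested lists passed either, under camera, camera with an estimated correlation or fry. Cholesterol synthesis genes had a median of 0.22 over 22 members (camera adjusted p = 0.395), with Msmo1 at 83.9 FPKM in DMSO and 148 in PD, and with Fdps lower, at 7.83 and 4.16. p53 target genes had a median of -0.17 over 21 members (adjusted p = 0.395), with the cell cycle inhibitor Cdkn1a at 11.1 ± 1.43 FPKM in DMSO and 4.33 ± 0.805 in PD (SD, n = 2) and with Zmat3 at 3.62 and 1.43. Trophectoderm genes had a median of -0.44 over 5 members, with Krt19 at 5.34 and 1.75 FPKM. Neural genes had a median of 0.31 over 4 members, with Stmn2, a microtubule regulator, at 127 ± 7.61 FPKM in DMSO and 273 ± 13.5 in PD (SD, n = 2). Mesoderm and endoderm genes had a median of 0.32 over 4 members that went both ways: the laminin chain Lamb1 had 62.3 FPKM in DMSO and 26.6 in PD, whereas Col4a1 had 0.92 and 3.86. Stmn2, and Lamb1 and Col4a1, passed when adjusted over the list alone, although 0 members passed over all genes. The same held for 3 methylation-sensitive germline genes: Rhox6 and Rhox9, listed at 0 in both PD libraries and at 3.17 to 4.37 FPKM in DMSO, and Tuba3a, at 1.83 and 8.06 FPKM. Rhox9 had 2 and 3 recovered reads in the DMSO libraries, and Rhox6 had no recovered reads. The germline list had a median of -0.16 over 11 members, and of 0.00 without the genes listed at 0.

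Genes of growth and metabolism showed no common direction. The medians were -0.09 for 59 cytosolic ribosomal protein genes and -0.09 for 42 ribosome biogenesis genes. They were 0.04 for 44 translation initiation and elongation factors, 0.01 for 20 glycolysis genes, 0.03 for 28 ATF4 and amino acid response genes, 0.00 for 49 nuclear-encoded respiratory chain genes and 0.03 for 40 cell cycle genes. Their camera adjusted p-values all lay at 0.864 or above. Within them, Eif3m had 85.8 FPKM in DMSO and 167 in PD, Eif5a had 171 and 107, Sdhc had 202 and 333, and Atf5 had 4.55 and 0.303. Ribosomal protein genes and Gapdh have many processed copies in the mouse genome, and Gapdh was listed at 4.96 and 1.37 FPKM in the DMSO libraries, so values of such genes are uncertain. DNA methylation machinery had a median of 0.15 over 12 members, with Mbd2 at 3.12 FPKM in DMSO and 0.141 in PD. Feeder and fibroblast markers, which other cells in the dish would bring, had a median of -0.04 over 8 members. Among them Vim stood at 105 and 29.7 FPKM in the DMSO libraries and at 207 and 185 in the PD libraries. Abundant noncoding RNAs had a median of 0.18 over 13 members, and 3 replication-dependent histone genes had one of -0.04. In the rescaled table, which moved the median of all genes from -0.02 to 0.14, the medians of the core pluripotency (0.07), mesoderm and endoderm (-0.58), neural (-0.99), MEK-ERK pathway (0.29), ribosome biogenesis (0.23) and feeder (0.32) lists had the other sign. Quantile normalization turned those of the respiratory chain (-0.03) and feeder (0.01) lists. With no filter on low values, the medians of the neural genes (-0.05), nuclear-encoded respiratory chain genes (-0.01) and feeder and fibroblast markers (0.01) turned, and with a filter of 5 FPKM those of the mesoderm and endoderm genes (-0.14) and the respiratory chain. Voom turned the germline, MEK-ERK pathway, respiratory chain, cell cycle and feeder lists. Without DMSO replicate 1 the germline, DNA methylation, cytosolic ribosomal protein, ribosome biogenesis, glycolysis, ATF4 and feeder lists turned, and without DMSO replicate 2 the trophectoderm genes (0.02) and the translation factor, respiratory chain and noncoding RNA lists. Without PD replicate 1 the translation factor, ATF4 and histone lists turned, and without PD replicate 2 the p53 target genes (0.03) and the germline, cytosolic ribosomal protein, ribosome biogenesis and glycolysis lists. None of these lists passed in any setting. The median and the mean of the list differed in sign for the ATF4, cell cycle, feeder and noncoding RNA lists.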

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

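The protein-coding gene subset, voom on recovered reads and the estimated correlation in 2 further settings of the naive list were chosen after the data were seen. The numbers of genes that passed (3 higher and 22 lower in PD) stayed within 1.5 times under the other pseudocounts, filters, scalings, variance settings and threshold, with 2 to 3 higher and 19 to 25 lower, and with the replicate block, which gave 2 and 17. No gene passed without small RNA, unnamed, mitochondrial and histone genes (0 higher, 0 lower), among protein-coding genes only (0 and 0) or with voom (0 and 0); each of these leaves out every gene that passed, the last for having too few recovered reads (20 genes) or none recovered (5 genes). Leaving out each library gave 0 to 27 higher and 0 to 30 lower, and the lone library of a group is then assumed to vary like the others. The naive pluripotency list passed with no filter on low values (median 0.30, camera adjusted p = 0.0206), where more genes form the background, and over the 4 left-out libraries its median was 0.16 to 0.39, past the threshold only without DMSO replicate 1. With an estimated correlation both calls were lost (adjusted p = 0.984 and adjusted p = 0.919), as in the main setting (adjusted p = 1.00). The median of the mRNA decapping and decay factors, never past the threshold, was 0.0434 with quantile normalization, 0.25 without small RNA and the other genes above, 0.0313 with voom and -0.0297 to 0.0969 over the left-out libraries. The cause was not tested. That rescaled table moved the median of all genes from -0.02 to 0.14. The ERK list and the formative and primed list kept their direction and did not pass in any setting, and 0 of the other lists passed in any. For named genes, 1952 values under alternatives kept their sign and side of the threshold, and 49, none of them past it, turned their sign. Replicate numbers share no label beyond the number, and the differences between replicates 1 and 2 in DMSO and in PD correlated at r = 0.0992 across all tested genes, at 0.204 across protein-coding genes and at 0.352 across those with a mean of at least 20 FPKM. With 2 pairs, this leaves open whether same-numbered libraries were made together. The block changed no call of a gene list.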

Other observations

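The counting tests for the miRNA and snoRNA genes and for Epcam and Cldn6, the tests of depth on the epithelial list, and those on the naive list without each library, were chosen after those results were seen. The epithelial list was also drawn up after. Its members were fixed before their values were examined, except Lsr, which was already among the genes with the largest downward differences. The tests on the naive list with all libraries, on protein-coding genes listed at 0 and on chromosomes were set before their result was seen.

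Epithelial junction and polarity genes lay lower in PD as a list. The list was drawn up because Epcam, Cldn6 and Ap1m2 were among the genes with the largest downward differences, and it leaves out these 3. Of its 24 tested members, 20 had an estimate below 0, 15 had both PD libraries below both DMSO libraries and 2 had both above. The median log2 difference was -0.89. E-cadherin (Cdh1) had 110 and 123 FPKM in the DMSO libraries and 60.6 and 58.1 in the PD libraries. The splicing regulator Esrp1 had a mean of 8.37 FPKM in DMSO and 1.4 in PD. Cldn7 stood at 6.3 and 6.97 against 1.78 and 0 FPKM, and the protease St14 at 6.74 and 7.4 against 3.78 and 2.81. Cxadr and Llgl2 went the other way, the latter at 6.4 and 8.63 against 12.1 and 10.3 FPKM. No member passed on its own. Lower levels of such genes as a set passed limma's camera with the preset correlation (adjusted p = 7.46e-05 over 24 lists, and adjusted p = 0.000374 without Lsr, itself among the named genes with the largest downward differences). Because the list was drawn up after 3 like genes were seen low in the same libraries, this p is not an independent test. The other 23 lists were fixed before.

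The call for the epithelial list was lost with an estimated correlation (adjusted p = 1.00), with fry (adjusted p = 0.848), with voom (median -0.44 over 13 members, adjusted p = 0.153), in the rescaled table without small RNA genes (median -0.80 over 34 members, adjusted p = 0.0886) and among the 14 members with at least 5 FPKM (median -0.27, adjusted p = 0.271). It held without each library in turn, with medians from -0.89 to -0.39. Epcam and Cldn6 had 151 of 1824 and 51 of 610 reads in PD. Their reads were divided by 2.82, the most that the variance between replicates exceeded binomial counting at 5 to 19 reads. Counting error of that size is argued against (larger exact binomial p times 9741 genes = 0.00305). At 500 to under 2500 reads in DMSO, where both genes lie, the factor was 33.9, and the test was not run with it. Variation between libraries of that size therefore stays open for these 2 genes, and lower depth was not separated from it. Ap1m2 had no recovered reads. For the list, a shift that depth gives to genes of like FPKM is argued against as the whole source. The list's median lay below all 10000 random lists matched on mean expression and, without each library in turn, at the 0.04 percentile or lower. The random lists were not matched on reads, their genes were drawn independently, and the PD libraries stayed the shallower in every subset. The smaller medians without PD replicate 2 (-0.39) and at 5 FPKM or more (-0.27) leave a part for depth open. A candidate explanation is that PD lowers the footprints of epithelial transcripts, through their mRNA or their translation. A difference between cultures or library preparations that goes with the groups stays open as untested, as does a shift in cell makeup. Trophectoderm genes had a median of -0.44 over 5 members, whose sign turned without DMSO replicate 2. Feeder and fibroblast markers had a median of -0.04, with 4 estimates above 0 and 4 below. Vim had 105 and 29.7 FPKM in the DMSO libraries and 207 and 185 in the PD libraries. S100a6 had means of 42.7 FPKM in DMSO and 20 in PD.

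Few reads were recovered for the genes that passed. Of the 22 lower genes, 17 had recovered reads. Taken as they are, these are too few to test one by one, since even 8 reads, all in DMSO, give an exact binomial p of 0.215. They are the smallest whole numbers that fit, and the true reads may be a multiple. At 389.258 FPKM in DMSO replicate 1, Mir196b had 1 recovered read and Mir1224 had 3. The other 5 lower genes had no recovered reads and stay open. Of 393 miRNA and snoRNA genes with recovered reads, 22 were listed at 0 in both PD libraries and above 0 in both DMSO libraries. Depth alone gave 30.3 (22 to 39 in 95% of 10000 draws). Recovered reads that are too low raise the number that depth gives, so this cannot decide whether counting is the source of the zeros. For Mir8109 and Mir378b, with 7 and 2 recovered reads taken as they are, counting and a real difference cannot be told apart. All reads in PD still give no less than 0.213 (smaller exact binomial p times 9741 genes). For Mir3064 the product is 9.96e-05 with its 12 reads taken as independent molecules, but 1 with reads divided by 4.13, the like factor for miRNA and snoRNA genes, so counting stays open there too, and reads from an overlapping host transcript remain untested.

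The naive pluripotency list lay at the 100th percentile of 10000 random lists matched on mean expression, whose central 95% ran from a median of -0.22 to 0.15. Without PD replicate 2 it lay at the 99.36 percentile and without DMSO replicate 1 at the 99.97, but without PD replicate 1 (median 0.19) it lay at the 97.24 and without DMSO replicate 2 (median 0.16) at the 96.52, inside the central 95%. With all libraries the list met the bar set before against lower depth, a median above the central 95%, and the random lists centred at -0.02. The checks without each library came after and did not all meet that bar. Lower depth as the source of the list's median of 0.30 is therefore not settled and stays open. The formative and primed list lay at the 0.27 percentile and the ERK list at the 3.92 percentile. These describe the 4 libraries, and with an estimated correlation none of the lists passed. An effect of PD on the balance of naive and later states is a hypothesis that may be followed up with deeper libraries.

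Protein-coding genes listed at 0 in both PD libraries and above 0 in both DMSO libraries numbered 647 among those with recovered reads, against 44 the other way, a ratio of 14.7, where depth alone gave 541 and 11.3, a ratio of 48. Recovered reads that are too low raise both of these expected numbers, yet both lay below the numbers seen. These values argue against binomial counting at these depths as the whole source of the zeros in either group. Depth alone gave a larger asymmetry than was seen. How reads that are too low move that ratio was not tested, so lower depth stays open as the source of the asymmetry. By chromosome, the largest shift of protein-coding genes was -0.0741 log2 units, on chromosome 15 (permutation p = 0.006, adjusted p = 0.12 over 20 chromosomes), far from a gain or loss of a whole chromosome.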
